A study of Mus musculus with 4 samples.

How the data were processed

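The series holds RNA sequencing of mouse brain endothelial cells at embryonic days 15 (E15) and 18 (E18). Wild-type embryos were set beside UCP2f/f;Tie2-cre embryos, in which a floxed Ucp2 gene is exposed to Cre recombinase from the Tie2 promoter, active in endothelial and most blood cells. Per the labels, the strain was C57BL/6, total RNA was extracted with Trizol and libraries were sequenced by a standard Illumina protocol. How the cells were isolated is not given in the sources used here. Stage and genotype of each library were taken from the labels. The 4 libraries analysed here form 4 groups of 1 library each, although the series' design text speaks of replicates.

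The authors deposited a table for each stage with the knockout and the wild-type library side by side. Per the file headers, each table gives raw read counts per Ensembl gene, not normalized, and the values are whole numbers with a different total in each library. The authors' normalized values are CPM, read counts scaled to the same library total, in which a count of 0 is set to the value of 0.5 read. The deposited fold is the ratio of the knockout CPM to the wild-type CPM, and the deposited log2 value is its logarithm. The authors' p-values and adjusted p-values stand beside each fold. The test behind them is not given in the sources used here, and it had 1 library on each side. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0, without their roles, and the genome build mm9. Of 20143 gene identifiers found in the GENCODE M21 annotation, which is on GRCm38, 18140 (90.1%) had the identical start and end in the deposited tables, so coordinates are printed as the tables give them and read as GRCm38. Whether counting used strand is not given in the sources used here, so genes that overlap on opposite strands may share reads. Genes with near-identical copies may have lost or exchanged reads in the same way.

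At E15 19031 genes are listed and at E18 17344, with 16181 in both. Library totals were 15542930 and 16328300 reads for the wild-type and knockout libraries at E15, and 19075407 and 21992660 at E18. The authors' CPM implies that between 0.00481% and 0.0195% of reads per library lay in genes outside the table. Counts of the genes in both tables gave the TMM factors of edgeR 4.0.16 (1.04, 1.04, 0.959 and 0.961 in the same order), with library totals over all listed genes.

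For each comparison of 2 libraries, the log2 ratio of TMM-scaled CPM was computed with a pseudocount of 1 CPM, which understates the differences of weakly expressed genes. Genes entered with at least 1 CPM in a compared library and at least 50 reads over both. The comparisons between stages took only genes listed in both tables, so their calls and highest genes hold for these alone. A gene is called higher or lower at a 2-fold ratio on this scale. With 1 library per group there is no replicate check and no p-value; a call compares libraries, not conditions. Intervals are exact Clopper-Pearson 95% intervals of the ratio of scaled counts, without the pseudocount, so that for genes with few reads they can lie outside the log2 ratio itself. Intervals and floors cover counting error only. Where a library had 0 reads, the fold is a bound against a floor of 3 reads in that library. Counts were simulated for 10026 genes with a mean of at least 5 CPM, 200 of them changed 4-fold. The procedure called 100% of the changed genes with 0 false calls for the E15 and the E18 genotype comparison. The intervals covered the true ratio in 95.8% and 94.9% of genes. Weaker genes, which also entered the comparisons, were not simulated, so these shares do not cover them. The simulated counts carried counting error only, without variation between samples, so they do not give the false calls to be expected between libraries.

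Gene lists for cell types, pathways and complexes, 42 in all, were fixed before the data were examined. A list with at least 5 measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these libraries only. A list stands outside the central 95% below percentile 2.5 or above 97.5. Functional terms carried in the deposited tables, with 15 to 300 measured genes, were treated alike.

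The additive test used edgeR's quasi-likelihood F test (glmQLFit, glmQLFTest) on all 4 libraries with stage and genotype as terms and Benjamini-Hochberg adjustment, on genes with at least 1 CPM in at least 2 libraries. The 2 stages serve as the replicates of the genotype effect and leave 1 residual degree of freedom. The difference between the genotype effects of the 2 stages fills it, moderated across genes with 6.09 prior degrees of freedom. The p-values and the dispersion therefore count a knockout effect particular to a stage as noise, and do not measure the spread between embryos of a group. The common dispersion was 0.111, a biological coefficient of variation of 33.3%. In counts simulated for this test at that dispersion (13416 genes, 100 changed by each fold) it recovered 5% of 2-fold and 55% of 4-fold changes, with 1 false call. At a dispersion of 0.01 it recovered 100% of both, with 11 false calls.

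Genes are named by a rule fixed before the data were examined. It takes Ucp2, and per genotype comparison the 10 highest and 10 lowest genes with at least 5 CPM in a library, passing over provisional symbols. It adds the 10 genes per direction with the largest smaller ratio among those past 2-fold in one direction at both stages, and the 5 per direction in each stage comparison. Per described list it takes the 2 members with the largest ratio and the 2 with the highest expression, of which some are printed. It ends with the genes with the smallest adjusted p in the additive genotype test, up to 5 per direction. Some genes taken by the rule are not reported here. Pecam1 in the figure, as an endothelial marker, and Kcnq1, as a neighbour, stand outside the rule. Any other gene named outside it in the report is said to have been chosen after its values were seen.

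The alternatives fixed in advance were median-ratio size factors, plain totals, the authors' CPM, library sizes without haemoglobin, mitochondrial and ribosomal RNA genes. Further ones were pseudocounts of 0.25 and 5 CPM, no filter beyond 1 read, a filter at 5 CPM, random lists without matching, and for the additive test DESeq2 1.42.0 and voom from limma 3.58.1. Centring the ratios by transcript length or by GC content in 20 bins, and leaving out genes on X and Y, were chosen after seeing the data. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not realigned, so exon-level reads over the deleted part of Ucp2 were not analysed here.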

Results

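Transcripts of brain endothelial cells were counted at E15 and E18 in wild-type embryos and in embryos with Cre-mediated deletion of Ucp2, which encodes a carrier of the mitochondrial inner membrane. The series concerns endothelial UCP2 around the time when the developing brain turns from making neurons to making astrocytes. Each of the 4 groups held 1 library, with 15542930 and 16328300 reads in genes for the wild-type and knockout libraries at E15, and 19075407 and 21992660 at E18. The genotype was compared at each stage, the stages within each genotype, and the effects shared across libraries with an additive test. There were no replicates, so each ratio below describes a pair of libraries and its 95% interval covers counting error only.

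Ucp2 (ENSMUSG00000033685, chromosome 7, 100493337 to 100502020) was lower in the knockout library at both stages and was still detected in both knockout libraries. At E15 it had 4285 reads in the wild-type and 2666 in the knockout library (264 and 157 CPM), a log2 ratio of -0.75 with an interval of -0.82 to -0.68. At E18 it had 6696 and 3296 reads (366 and 156 CPM), a log2 ratio of -1.22 with an interval of -1.29 to -1.17. The wild-type library at E18 stood above that at E15 (log2 0.47, interval 0.42 to 0.53), whereas the knockout libraries were at the same level (log2 -0.01, interval -0.08 to 0.06). Which exons are deleted is not given in the sources used here, so reads from undeleted exons and from cells without Cre can remain in these counts. Dnajb13, chosen after its values were seen, overlaps the end of Ucp2 and had 48, 33, 39 and 4 reads in the wild-type and knockout libraries at E15 and then E18.

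**Figure D1:**
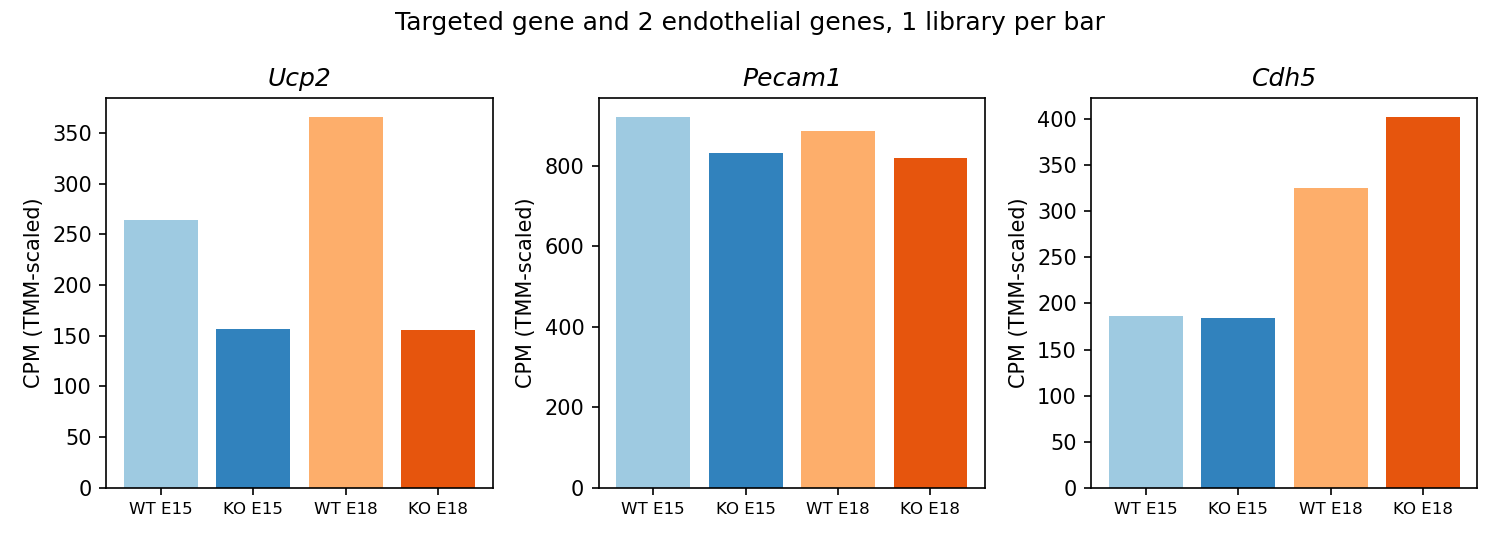
Expression of Ucp2 and of the endothelial genes Pecam1 and Cdh5, as TMM-scaled CPM on axes that start at 0, with 1 library per bar and no error bars because no group had replicates. The Ucp2 bars stand at 264 and 157 CPM for the wild-type and knockout libraries at E15, and at 366 and 156 CPM at E18.

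At E15, transcripts of neurons, mural cells, fibroblasts and microglia were lower in the knockout library, and those of respiratory chain subunits encoded in the nucleus were slightly higher. With the pseudocount of 1 CPM, the transcription factor Cebpd had the highest ratio of the named genes, with 68 reads in the wild-type and 1308 in the knockout library (log2 3.91, interval 3.85 to 4.57). Hes1, a transcriptional repressor induced by Notch, had 1341 and 9076 reads (log2 2.68, interval 2.61 to 2.78). The transcription factor Tbx1 (34 and 504 reads, log2 3.31), the phosphatase Ppm1d (log2 2.59) and Syap1 (297 and 1825 reads, log2 2.49) were also among the 10 highest. In all, 447 genes were called higher and 401 lower among 12633 (6.71%).

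The other genes of the 10 highest at E15 were Rab6b (8 and 212 reads, log2 3.18), Bloc1s4 (41 and 469 reads, log2 3.02), Fgfbp3 (log2 2.62), and a pair without wild-type reads. Tnfrsf8, the receptor CD30, was at least 29.3-fold higher and Adamts14, a procollagen-processing protease, at least 28.4-fold higher. Among the lowest, Ttr, a thyroid hormone carrier made in bulk by the choroid plexus, had 202 reads in the wild-type and 5 in the knockout library (log2 -3.38, interval -7.04 to -4.15). The ephrin receptor Epha5 was at least 33.1-fold lower and the zinc finger gene Zfp990 at least 53.3-fold lower, and the synaptic adhesion gene Nrxn3 had 113 and 6 reads (log2 -2.56). The matrix proteoglycan Ogn had 99 and 3 reads, Trim12a 97 and 1, and Tnfrsf14 126 and 8. Eno1b (2960 and 25 reads, log2 -6.21) is a near-identical copy of Eno1, and Xlr4a (at least 55.1-fold lower) and Xlr3a (at least 29.3-fold lower) belong to a multigene family on X, so these are uncertain.

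Of 37 lists measured at E15, 12 had medians outside the central 95% of matched random lists. The neuronal list had a median of -0.93 (percentile 0.0), with 15 of 16 members below 0 and 7 called lower. Neurod6 had 418 and 201 reads (log2 -1.06) and Celf4, an RNA-binding protein, 119 and 39 (log2 -1.34). Microglial and macrophage genes had a median of -0.73 (percentile 0.0), with 15 of 17 below 0, including the chemokine receptor gene Cx3cr1 (1416 and 377 reads, log2 -1.93) and Csf1r (2459 and 1049 reads, log2 -1.28). Mural cell genes had a median of -0.59 (percentile 0.0), with 11 of 12 below 0, among them Rgs5 (79709 and 55530 reads, log2 -0.59) and Notch3 (log2 -1.10). The fibroblast and meningeal list stood at -0.74 (percentile 0.01), with 6 of 7 members below 0, such as the collagen gene Col3a1 (3368 and 1555 reads, log2 -1.17).

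Pan-endothelial genes as a group did not stand apart at E15 (median 0.00, percentile 55.8), although Flt1, a receptor of vascular endothelial growth factor, had 20645 and 47988 reads (log2 1.15). The blood-brain barrier list had a median of 0.14 (percentile 99.8), with 18 of 22 members above 0. Its transcription factor Foxq1 had 540 and 1534 reads (log2 1.41), and the glucose transporter Slc2a1 a log2 ratio of 0.07. Targets of Wnt and beta-catenin had a median of 0.22 (percentile 99.04), with 9 of 10 above 0, led by the feedback inhibitor Nkd1 (5395 and 13405 reads, log2 interval 1.20 to 1.29). Basement membrane genes had 13 of 16 members below 0 (median -0.16, percentile 1.12), including Col18a1 (log2 -0.80) and Col4a1 (log2 -0.30). The list of endothelial factors that act on neural progenitors had a median of -0.15 (percentile 1.98), with 16 of 25 below 0. At E18 its median was 0.06 (percentile 77.5). Its largest ratio at E15 was that of Dll1 (64 and 3 reads, log2 -2.07). Dll1 is also in the neural progenitor list and Igf2 in the fibroblast list, so the median need not reflect endothelial cells alone. Igf1 had 180 and 77 reads (log2 -1.13) and Cxcl12 a log2 ratio of -0.18.

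Subunits of respiratory complex I had a median of 0.30 at E15 (percentile 100, 31 of 34 above 0) and those of complexes II to IV a median of 0.25 (percentile 99.8, 20 of 24 above 0). The most abundant members lay near 0, with Ndufv1 at 0.07 and Sdha at -0.13. Ndufs3 had 37 and 94 reads (log2 1.00) and Cox5a 91 and 178 (log2 0.80). Proteins encoded by the mitochondrial genome were lower in 10 of 10 members (median -0.34, percentile 0.02), among them mt-Nd4 (log2 -0.46) and mt-Co1 (79026 and 66423 reads, log2 -0.32). Genes of the G2 and M phases were below 0 in 15 of 20 (median -0.16, percentile 0.97), with Top2a at -0.42. Of the lists that bear on metabolism, ATP synthase (0.08, percentile 80.8, 8 of 14 above 0) and the tricarboxylic acid cycle (0.00, percentile 54.4) lay inside the central 95%. So did glycolysis (0.03, percentile 73.0), fatty acid oxidation (0.12, percentile 96.3) and the antioxidant response (-0.01, percentile 47.6). Gclm, which supplies a subunit of the rate-limiting enzyme of glutathione synthesis, nevertheless had 217 and 1169 reads (log2 2.28). Short transcripts were higher in this pair (median 0.09 in the shortest 10% of genes). After centring by length, chosen after the values were seen, complex I stood at 0.20 (percentile 99.6) and complexes II to IV at 0.20 (percentile 99.2), while the basement membrane list lay inside the central 95% (-0.12, percentile 3.49). The calls at E15 depend on weakly expressed genes: a pseudocount of 5 CPM left 161 higher and 68 lower, no filter gave 701 lower, and a filter at 5 CPM 238 lower. Against random lists without matching, 7 lists instead of 12 stood outside the central 95%.

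At E18, immediate early and interferon genes were lower in the knockout library, and cell cycle and microglial genes were higher. The libraries also differed in sex-specific transcripts. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 5826, 821, 499 and 314 reads in the wild-type library and 0 in the knockout library, at least 2.24e+03-fold, 316-fold, 192-fold and 121-fold lower. Xist, the X-inactivation transcript, had 0 reads in the wild-type and 547 in the knockout library, at least 158-fold higher. At E15 both libraries held Xist reads (2549 and 2109). The Y-linked genes had no values at E15 and were not analysed there. The authors' CPM implies 3032 and 2300 reads in all genes outside the E15 table together, for the wild-type and knockout libraries. Each total is below the 5826 reads of Ddx3y alone in the wild-type library at E18, by more than the difference in depth. A sex difference like that at E18 is therefore argued against at E15. Genotype and sex cannot be separated at E18. The calls comprised 362 higher and 492 lower genes among 12349 (6.92%), of which 14 and 26 lay on X or Y.

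Besides Xist, the highest genes at E18 included several of immune cells: the mast cell protease genes Cpa3 (0 and 252 reads, at least 72.8-fold higher) and Tpsb2 (at least 30.6-fold higher) and the microglial gene Tmem119 (at least 31.2-fold higher). Ttr had 0 reads in the wild-type and 180 in the knockout library, at least 52-fold higher, the opposite of E15. Also among them were Tmc5 (at least 47.1-fold higher), Fam161b (5 and 180 reads, log2 2.90), Asprv1 (15 and 194 reads, log2 2.48) and C1qtnf12 (45 and 375 reads, log2 2.44). Besides the Y-linked genes, the lowest were Ttc12 (287 reads and 1 read), the protocadherin Pcdhb8 (at least 57.3-fold lower), Nol4 (at least 51.2-fold lower), the deubiquitinase Usp35 (at least 40.4-fold lower), Zfp420 (421 and 59 reads, log2 -2.66) and Setd4 (121 and 6 reads, log2 -2.57).

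Of 38 lists measured at E18, 12 had medians outside the central 95%, the sex-specific one among them (median -4.82, or -7.59 with the members without reads at their bounds, percentile 0.0). Immediate early and dissociation stress genes had a median of -0.59 (percentile 0.0), with 16 of 19 below 0. Fos had 131387 and 79624 reads (log2 -0.93), Jun a log2 ratio of -0.57 and Fosb 21964 and 8394 reads (log2 -1.59). Interferon response genes were below 0 in 16 of 17 (median -0.34, percentile 0.2), among them Mx2 (305 and 82 reads, log2 -1.86), Ifit3 (log2 -1.29) and Irf9 (log2 -0.29). Basement membrane genes were below 0 in 14 of 16 (median -0.21, percentile 0.14), with fibronectin, Fn1, at 23994 and 18224 reads (log2 -0.60) and Col4a1 at -0.37. Tip cell and angiogenesis genes had a median of -0.18 (percentile 0.31, 12 of 19 below 0), with Plxnd1 at -0.65.

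Genes of the S phase were above 0 in 18 of 20 at E18 (median 0.35, percentile 100), and those of the G2 and M phases in 16 of 20 (median 0.24, percentile 99.4). The replication gene Mcm3 had 3297 and 5573 reads (log2 0.55), the regulator E2f1 62 and 170 (log2 1.04) and the mitotic kinase Aurkb 852 and 1627 (log2 0.71), whereas Cenpf was lower (log2 -1.15). The unfolded protein response had a median of 0.21 (percentile 98.5, 11 of 14 above 0), with the chaperone Hspa5 at 15159 and 21278 reads (log2 0.28). Microglial and macrophage genes had a median of 0.68 (percentile 100, 13 of 14 above 0). Among them were lysozyme, Lyz2 (861 and 1863 reads, log2 0.89), and the protease Ctss (9 and 91 reads, log2 1.83). Csf1r, chosen here after its values were seen, went the other way (233 and 212 reads). Neuronal genes had a median of -0.61 (percentile 0.38, 12 of 15 below 0), with Stmn2 at 246 and 145 reads (log2 -0.88) but Map2 at 197 and 453 (log2 0.93). Astrocyte genes had a median of -0.26 (percentile 0.68, 9 of 15 below 0), with Gfap at 68 and 20 reads (log2 -1.28). Erythroid genes had one of -0.53 (percentile 0.3, 5 of 7 below 0), with the haem synthesis gene Alas2 at -0.57. Pan-endothelial genes (-0.06, percentile 7.97), the blood-brain barrier (0.00, percentile 37.7), respiratory complex I (0.04, percentile 69.1) and mitochondrially encoded proteins (-0.12, percentile 12.4) did not stand apart. Long transcripts were lower in this pair (median -0.16 in the longest 10% of genes). After centring by length, an alternative chosen after the values were seen, the basement membrane (-0.09, percentile 5.09), unfolded protein response (0.14, percentile 93.7) and astrocyte lists (-0.16, percentile 3.78) lay inside the central 95%. The mural cell, glycolysis and hypoxia lists then lay outside it (percentiles 98.5, 0.36 and 0.74). A filter at 5 CPM brought the neuronal median to -0.08 and the microglial one to 0.49, with an order-statistic interval of -0.32 to 1.18 that holds 0. Without a filter the erythroid median was 0.04. A pseudocount of 5 CPM left 46 genes higher and 84 lower, no filter gave 578 and 912, and a filter at 5 CPM 219 and 287.

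**Figure D2:**
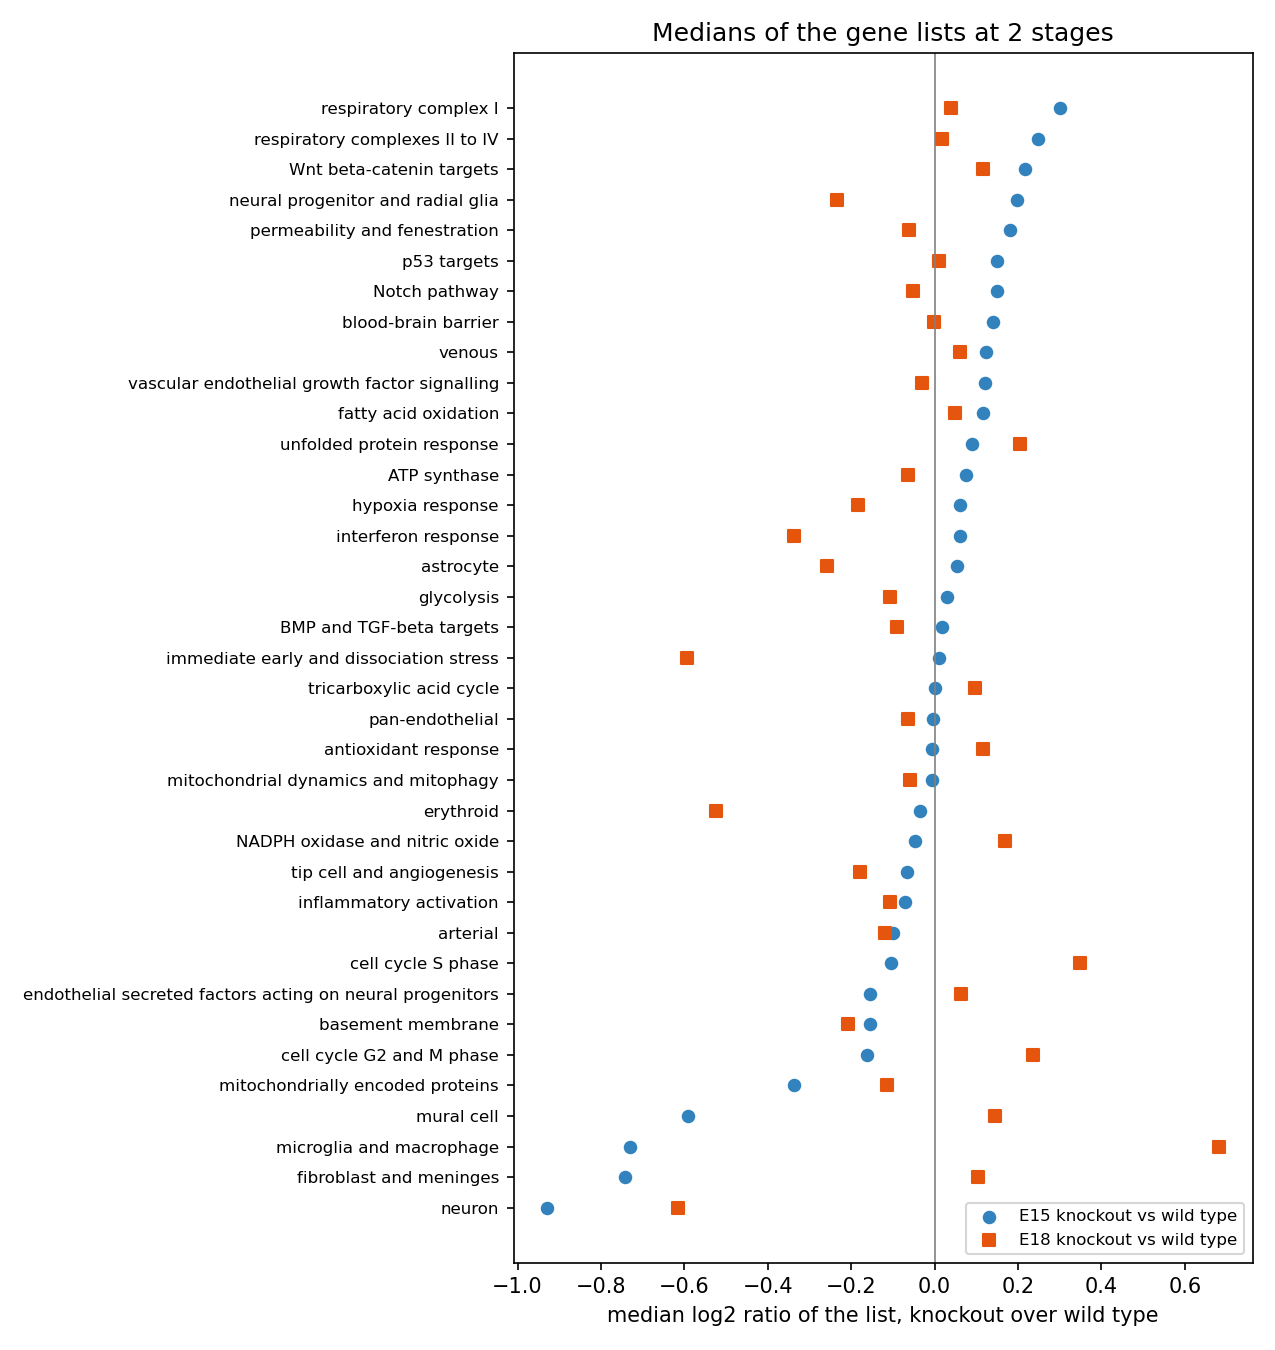
Median log2 ratio, knockout over wild type, of each fixed gene list with at least 5 measured genes at both stages. Circles stand for E15 and squares for E18, sorted by the value at E15. The sex-specific list, described at E18 only, is not drawn. The neuronal list lies lowest at E15 (-0.93) and respiratory complex I highest (0.30), and the microglial list lies at -0.73 at E15 and 0.68 at E18.

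Across 11784 genes measured at both stages, the 2 genotype ratios were nearly unrelated (Pearson r 0.042, Spearman rho 0.043, across genes, which are not independent replicates). Among the genes past 2-fold at both stages were Sumf1, the activator of sulfatases (244 and 1502 reads at E15, 83 and 528 at E18, log2 2.48 and 2.23), and the ubiquitin ligase gene Rnf187 (2050 and 6459, 676 and 2500 reads, log2 1.58 and 1.65). Cpa3 (11 and 114 reads at E15), the neutrophil granule gene Ngp (1 read and 83, then 53 and 284), Tnfrsf8 (0 and 62 reads at E18), Fam149a (log2 2.02 and 1.72), Tmem160 (1.62 and 1.94), Col9a2 (1.52 and 2.14), Fam105a (1.56 and 1.47) and the potassium channel gene Kcnn3 (12 and 78, 1 read and 50) were also higher at both. Lower at both were Xlr3b (365 and 62, 595 and 125 reads, log2 -2.34 and -2.28, uncertain as a member of its family), Trim2 (log2 -1.81 and -2.33), Celf4 (-1.34 and -1.49), Sema5b (-1.30 and -1.50), Kif21a (179 and 69, 219 and 32 reads), Osbpl5 (-1.53 and -1.31), Zfp607b (-1.47 and -1.41), Xlr4a (at least 24.2-fold lower at E18) and Fcho1 (58 and 2, 64 and 0 reads).

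In all, 40 genes were called higher at both stages where 1000 permutations within expression bins gave 15.6 on average (range of the central 95%, 9 to 23), and 37 were lower at both (24.6, 16 to 34). Opposite calls were also in excess in one direction: 37 genes were lower at E15 and higher at E18 (17.0, 10 to 25), and 20 were higher at E15 and lower at E18 (22.7, 15 to 31). Of 1479 functional terms, regulation of cell migration alone lay in the lowest 0.5% at both stages (medians -0.16 and -0.22, 47 and 45 genes). In the highest 0.5% at both stages lay 0 terms, and independence would give 0.037 in each direction. The random lists were matched on expression, not on transcript length. The longest 10% of genes had medians of -0.045 at E15 and -0.16 at E18. A length trend shared by both pairs therefore stays open for this term, and independence leaves it out.

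**Figure D3:**
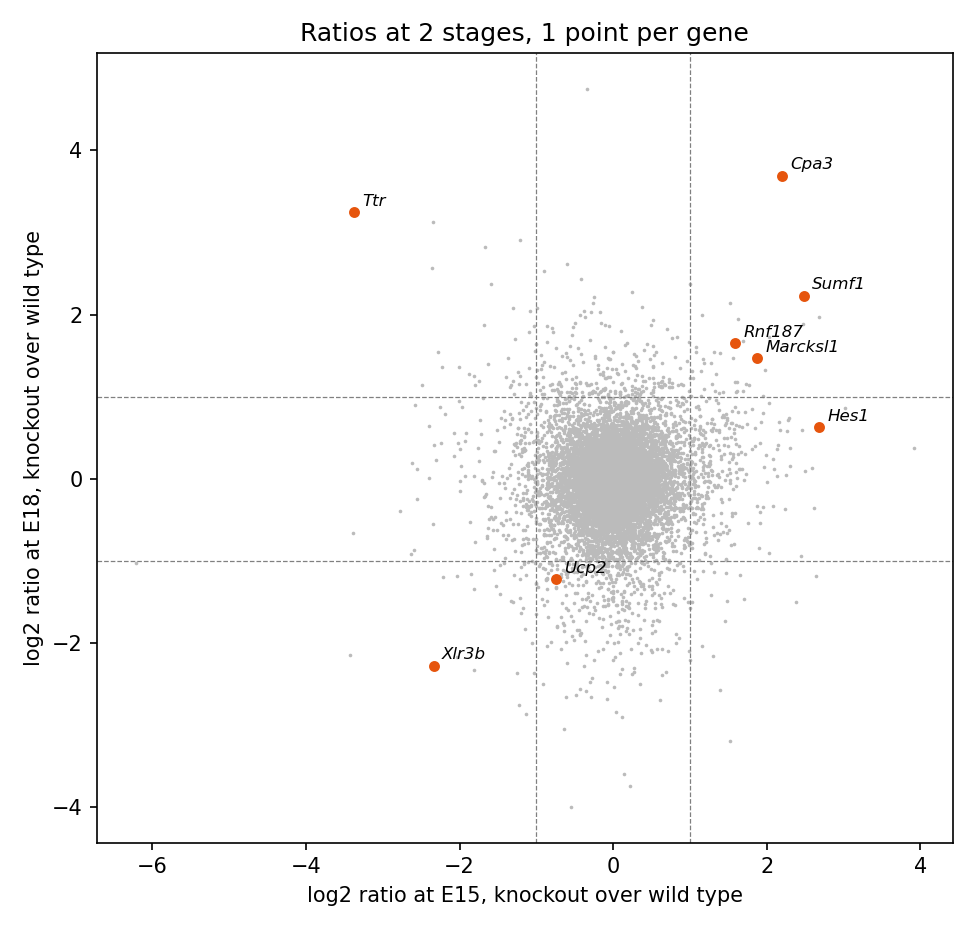
Log2 ratio of knockout over wild type at E15 (horizontal axis) and at E18 (vertical axis), with 1 point per gene measured at both stages and dashed lines at the limits of a call. The ratios at the 2 stages are nearly unrelated (Pearson r 0.042). Sumf1 and Rnf187 lie past the lines on the higher side at both stages.

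In the additive test of genotype across both stages, 3 genes rose in the knockout and 0 fell among 13416 tested by edgeR: Rnf187 (ENSMUSG00000020496, chromosome 11, 58932288 to 58938916) by 1.63 on the log2 scale, Sumf1 (ENSMUSG00000030101, chromosome 6, 108107028 to 108185582) by 2.51, and the actin-binding MARCKS relative Marcksl1 (ENSMUSG00000047945) by 1.68. Each had a Benjamini-Hochberg adjusted p of 0.0484 and was higher at both stages. The test favours genes whose ratios agree between stages, so that agreement is no separate support. All 3 were also called in the additive test of stage, lower at E18 (log2 -1.74, -1.79 and -1.80 for Rnf187, Sumf1 and Marcksl1). The wild-type library at E18 alone lacked Xist reads, so sex may also enter the genotype term. Marcksl1 had 3195 and 12327 reads at E15, and 1200 and 3864 at E18. At an unadjusted p under 0.05 there were 678 genes, DESeq2 called 47 (38 up, 9 down, with an adjusted p of NA for 5722 genes) and limma-voom 100 (80 up, 20 down); both included the 3. Without the expression filter edgeR called 0 (732 at an unadjusted p under 0.05, smallest adjusted p 0.0904). Among the fixed lists, 1 immediate early gene rose and 5 fell, and 1 Wnt target rose, when adjusted over the list alone, against 0 over all genes. The other lists had 0 by either count. The GC content of the longest annotated transcript was 61.1% for Rnf187, 58.2% for Marcksl1 and 49.4% for Sumf1, at percentiles 98.0, 92.2 and 50.3 of all genes.

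Between E15 and E18 in the wild type, interferon response genes were higher at E18 and microglial and cell cycle genes lower. All 16 measured interferon genes were above 0 (median 1.56, percentile 100), 13 of them past 2-fold, with Rsad2 at 82 and 1267 reads (log2 3.54, interval 3.45 to 4.12), Ifit1 at 36 and 506 (log2 3.15) and Irf9 at 1947 and 4506 (log2 1.03). Microglial genes had a median of -2.39 (percentile 0.0, 13 of 14 below 0), with P2ry12 at 1417 and 10 reads (log2 -5.84), Cx3cr1 at 1416 and 24 (log2 -5.25) and Csf1r at 2459 and 233 (log2 -3.47). All 20 G2 and M phase genes (median -0.74) and all 20 S phase genes (median -0.49) were below 0, both at percentile 0.0, with Mki67 at -1.50 and Rrm2 at -1.22. Also higher were Tnfsf10 (log2 3.03), Ifi213 (at least 42.9-fold higher, of a gene family and so uncertain) and Hba-a2 (3 and 152 reads, uncertain as a close paralog of Hba-a1). Also lower were Xist (2549 and 0 reads, at least 958-fold lower), Tmem119 (at least 221-fold lower) and Fcrls (1147 and 24 reads, log2 -4.95). Because of Xist, stage and sex cannot be separated in this comparison either. The wild-type library at E18 also enters the genotype comparison at E18. The interferon, immediate early, microglial and cell cycle results of both comparisons are therefore not independent.

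The blood-brain barrier list was higher at E18 in the wild type (median 0.38, percentile 100, 17 of 22 above 0), led by the monocarboxylate transporter Slc16a1 (2204 and 11760 reads, log2 2.23) and Slco1a4 (log2 2.04). Basement membrane genes were also higher (0.45, percentile 100, 13 of 16 above 0), with Col4a1 at 51529 and 102701 reads (log2 0.82). Mural genes (0.44, percentile 99.8) were above 0 in 13 of 13, with Rgs5 at 0.55. Immediate early genes had a median of 0.75 (percentile 100), with Fos at 1.38 but the heat shock gene Hspa1a at -2.12. Astrocyte (0.44, percentile 99.8, with Aldh1l1 at 2.21), neural progenitor (0.50, percentile 99.9, with Slc1a3 at 1.92), hypoxia (0.41, percentile 99.8, with Bnip3 at 1.49) and erythroid genes (0.90, percentile 100, with Hba-a1 at 1.54) were higher. Neuronal (-0.54, percentile 1.11, with Neurod6 at -1.66) and mitochondrially encoded genes (-0.67, percentile 0.0, with mt-Co1 at -0.67) were lower. The calls were 501 higher and 760 lower among 12515 genes (10.1%). Plain totals shift the median of all genes by -0.114 in this comparison and -0.097 in the knockout. With them the share of higher calls in the wild type was 28.9% instead of 39.7%, with the authors' CPM 28.9%, and without haemoglobin, mitochondrial and ribosomal genes 28.0%.

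In the knockout, E18 differed from E15 in the same lists of interferon (median 0.89, percentile 100, 15 of 16 above 0) and microglial genes (-1.22, percentile 0.0, 11 of 14 below 0), and mural and fibroblast genes were higher at E18. Mural genes had a median of 1.07 (percentile 100, 12 of 13 above 0), with Rgs5 at 55530 and 192751 reads (log2 1.48). Fibroblast genes had one of 0.94 (percentile 100, 7 of 7 above 0), with Igf2 at 1.34. The comparisons share libraries. Both lists were already lower in the knockout library at E15 than in the wild type (-0.59 and -0.74), so these ratios partly restate that result. Basement membrane (0.38, percentile 99.8, with Lama1 at 1.33) and astrocyte genes (0.35, percentile 98.6, with Mlc1 at 2.51) were higher. G2 and M phase (-0.48, percentile 0.03), mitochondrially encoded (-0.42, percentile 0.18), ATP synthase (-0.31, percentile 0.68, or 2.59 after centring by length) and Notch pathway genes (-0.29, percentile 0.88, with Hes1 at 9076 and 1453 reads) were lower. The named genes were Tnfsf10 (10 and 253 reads, log2 3.03), Ifi208 (at least 56-fold higher, uncertain), AI593442 (at least 49.3-fold higher), Tmc5 (at least 43.7-fold higher) and Eno1b (25 and 1919 reads, uncertain) on the higher side. On the lower side they were the imprinted antisense RNA Kcnq1ot1 (1049 and 66 reads, log2 -3.93, uncertain because it overlaps Kcnq1), the platelet gene Gp5 (at least 90-fold lower), Tbx1 (log2 -3.66), Pcdhb8 (at least 80.5-fold lower) and Rab6b (212 and 2 reads). The calls were 673 higher and 1171 lower among 12465 genes (14.8%). Long non-coding and unprocessed gene classes made up 38 of the higher and 216 of the lower calls. The share of higher calls was 36.5%, and 28.4% with plain totals, 28.5% with the authors' CPM and 27.9% without haemoglobin, mitochondrial and ribosomal genes.

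In the additive test of stage across both genotypes, 120 genes rose and 59 fell from E15 to E18 (edgeR, 2236 at an unadjusted p under 0.05). Among those with the smallest adjusted p (0.0148) were Slc16a1 (up 2.11 on the log2 scale), the interferon gene Ifi44 (up 2.48), Serpine2 (up 1.44) and Ly6c1 (up 1.61), chosen after their values were seen. Others with that adjusted p, likewise chosen, were Csf1r (log2 -3.11), Nkd1 (-1.51), Raly (-1.98), Ccnl2 (-1.66), Rnf187 (-1.74) and Marcksl1 (-1.80). Over all genes 7 interferon genes rose, and 11 when adjusted over the list alone. Likewise 5 blood-brain barrier genes rose and 1 fell (9 and 3 adjusted over the list alone), 4 microglial genes fell (8, with 1 up) and 2 basement membrane genes rose (12, with 1 down). Of G2 and M phase genes 0 fell over all genes and 12 when adjusted over the list alone; mural genes gave 1 and 8 up, and mitochondrially encoded genes 1 and 7 down. Stage cannot be separated from any batch in which the libraries of a stage were made. The wild-type library at E18 alone lacked Xist reads, so sex may also enter this test.

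The authors' deposited table calls 2022 genes up and 2342 down at E15, and 1554 up and 2849 down at E18, from a p-value that has no replicates behind it. In the authors' deposited table the adjusted p is under 0.05 for 61.1% of the genes at E15 and 72.9% at E18. The authors' deposited table gives Ucp2 a log2 fold of -0.76 at E15 (adjusted p 4.08e-101, not called) and of -1.23 at E18 (called). Of the genes called in the authors' deposited table, 1272 and 1354 pass the expression filter used here, all with the same sign, and 3092 and 3049 had fewer than 50 reads over both libraries. All 848 and 854 genes called here are also called in the authors' deposited table. Both folds come from the same counts with nearly equal scaling within a pair. The agreement in sign and calls was therefore all but fixed in advance and is no independent check.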

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

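The tests of explanations in this part were chosen only after the results they bear on were seen. Among the genes that the naming rule takes and that are reported here, 10 went past 2-fold one way at E15 and past 2-fold the other way at E18, knockout over wild type; with 1 library per group the differences were not tested. The rule fixed in advance covered gene lists only, of which none met it, and was extended to single genes after their values were seen.

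Ttr had a log2 ratio of -3.38 at E15 and 3.25 at E18, a difference of 6.63. Tmc5 had 66 and 0 reads at E15 and 0 and 163 at E18 (log2 -2.34 and 3.12, a difference of 5.46). Fam161b had 114 and 42 reads at E15 and 5 and 180 at E18 (-1.21 and 2.90, a difference of 4.11). The microglial genes Fcrls (-1.59 and 2.37, a difference of 3.96) and P2ry12 (-1.82 and 1.26, a difference of 3.08) and the interferon-inducible Ifi208 (-2.49 and 1.14, a difference of 3.63) went the same way. In the other direction, Pcdhb8 had 54 and 194 reads at E15 and 149 and 0 at E18 (1.52 and -3.19, a difference of -4.71). Setd4 had 29 and 107 reads, then 121 and 6 (1.39 and -2.57, a difference of -3.96), and Adamts14 0 and 89 reads, then 90 and 34 (2.64 and -1.18, a difference of -3.82). Ptgs2 had 1.27 and -1.02, a difference of -2.29.

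Markers of microglia, mural cells, neurons and fibroblasts were all lower in the knockout library at E15, with medians between -0.93 and -0.59. A smaller share of all other cells in that library cannot be told apart from other explanations. The medians of the 7 measured lists of other cells spanned 1.13. Neurons stood at -0.93 (95% order-statistic interval over the genes, -1.07 to -0.26) and neural progenitors at 0.20 (-0.68 to 0.64), and these intervals overlap. Sparcl1, in the astrocyte list, had 88140 reads in the wild-type library at E15, against 95601 for the endothelial gene Cldn5. Endothelial expression may enter such lists, so the span cannot decide the share of other cells. At E18 the span was 1.30, from neurons at -0.61 (-1.03 to -0.10) to microglia at 0.68 (0.26 to 1.18). With a filter at 5 CPM the neuronal median was -0.08 (-0.91 to 1.03) and the microglial one 0.49 (-0.32 to 1.18), and these intervals overlap. A different share of all other cells therefore stays open at E18 too. The filter moved the neuronal median itself, and whether the number of genes or their choice did so was not tested. Loss of microglia with otherwise unchanged expression cannot be told apart from other explanations at E15. The test took 7 abundant microglial genes that were at least 4-fold lower in the wild-type library at E18, so that expression in other cells weighs little. They spanned 3.00 log2 units, from Cx3cr1 at -1.93 to C1qc at 1.07, against a median span of 0.87 in random lists of like expression and outside their central 95%. Without C1qc, the farthest from their median, the span was 1.22 against 0.57, which did not pass that limit. A knockout effect on microglia, which may carry Tie2-cre as blood-lineage cells do, stays open as an untested hypothesis, and so does the purity of each preparation.

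At E18 there were 492 genes lower and 362 higher in the knockout library. A shift of the typical ratio with transcript length is argued against as the whole cause. After centring by length 476 were lower and 348 higher, and 438 were lower both before and after. Centring removes only the median of each length bin, so stronger losses among some long transcripts stay open. In the longest 10% of genes 79 were lower and 23 higher, and in the shortest 10% 33 were lower and 32 higher. Transcripts missed altogether are also argued against as the whole cause, because 48 of the lower genes had 0 reads in the knockout library and, with reads in both libraries, 444 were lower and 338 higher (56.8% lower, exact 95% interval 53.2 to 60.3). Weaker recovery of scarce transcripts in a less complex library cannot be told apart from other explanations. Among genes with at least 20 CPM in the wild-type library at E15, 58 were lower and 48 higher. That is 54.7% lower (44.8 to 64.4), which holds both an even split and the 57.6% of all calls. Less nuclear and unspliced RNA cannot be told apart either. Among protein-coding genes 387 were lower and 322 higher (54.6%, 50.8 to 58.3), and the excess went from 130 to 65 genes. Loci annotated as to be experimentally verified had a median of -0.80 at E18 (percentile 0.0, 37 lower and 6 higher). The 5 nuclear or unspliced classes as a whole had one of -0.16 (percentile 0.08, 85 lower and 28 higher). The medians of the other 4 lay inside the central 95%, although long intergenic RNAs (-0.07, percentile 36.1) had 25 lower and 11 higher and processed transcripts (-0.09, percentile 25.3) 12 and 3. The shift of the classes as a whole was not particular to this pair. Their median was 0.10 at E15, knockout over wild type (percentile 99.99). From E15 to E18 it was -0.26 in the wild type and -0.53 in the knockout, both at percentile 0.0. Among protein-coding genes with reads in both libraries and centred by length, 337 were lower and 289 higher, an excess of 48, so the explanations acting together are not excluded. An effect of the knockout, or of sex, also stays open and untested.

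Genes within 10 Mb of Ucp2 were called more often than elsewhere at E15 (16 of 123, 13.0%, against 6.7%), a ratio of 1.96 that 1.41% of windows of as many genes reached. Sequence of another strain carried along with the floxed allele is a candidate explanation. At E18, however, the ratio was 1.32, which 27.31% of windows reached. Between the wild-type libraries of the 2 stages it was 1.71, which 4.64% of windows reached. The strain sequence and ordinary clustering of called genes cannot be told apart, because each group held 1 library.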

How the results depend on the processing

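The alternatives that correct for transcript length or GC content, or leave out X and Y, were chosen only after the results were seen; the others were fixed in advance. Of 1588 values of single genes and lists under an alternative, 1561 held, 26 moved (20 of them with a pseudocount of 5 CPM) and 1 reversed. A gene held if it kept its direction and, where it had been past 2-fold, stayed so. A list held if its median stayed within its 95% order-statistic interval, which is wide for many lists. Whether a single list stayed outside the central 95% of random lists was not scored. Centring by length moved lists across that limit at both stages, as given above, so the count does not cover those results. Ucp2 stayed lower in the knockout library at both stages under all of them. A pseudocount of 5 CPM gave 161 genes higher and 68 lower at E15, 46 and 84 at E18, 190 and 211 between stages in the wild type and 243 and 492 in the knockout, because it shrinks ratios of weakly expressed genes; the correlation of the genotype effects was then 0.085, and 0.022 with 0.25 CPM. No filter gave 701 genes lower at E15, 578 higher and 912 lower at E18, and an erythroid median of 0.04 at E18 in place of -0.53. A filter at 5 CPM gave 238 lower at E15, 219 higher and 287 lower at E18, and a correlation of 0.081. Random lists without matching left 7 lists outside the central 95% at E15. The stage ratio of Ucp2 was 0.35 in the wild type and -0.12 in the knockout with plain totals, 0.35 and -0.12 with the authors' CPM, 0.34 and -0.13 without haemoglobin, mitochondrial and ribosomal genes, and -0.09 in the knockout with the GC correction. The additive test called 92 genes for stage without a filter, 724 with DESeq2 and 1171 with limma-voom, and for genotype 0, 47 and 100. Apart from the shrinkage named above, the cause was not tested. The additive test takes stage as a block, and no other pairing was possible because each group held 1 library. Leaving out a library was not run because 3 libraries leave no residual degrees of freedom. Depth limits genes below the 50-read filter, and for a gene with 0 reads it gives a bound only.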

Other observations

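The genes and counts in this part were singled out only after their values were seen, and no test was run on them. Some of these genes, such as Ttr, Cpa3, Ngp and Plvap, are also taken by the naming rule. Several other genes of the fixed choroid plexus and ependyma list, most with too few reads for a ratio, had 0 reads in the knockout library at E15, where Ttr had 5. In the order wild type and knockout at E15, then at E18, Aqp1 had 61, 0, 26 and 73 reads, Folr1 49, 0, 0 and 17, Kcne2 27, 0, 0 and 40, Otx2 8, 0, 0 and 14 and Foxj1 6, 0, 3 and 31. Aqp1 and Foxj1 were detected in the wild-type library at E18, where Ttr had 0 reads, and Clic6 (69, 43, 38 and 46 reads) in all 4.

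Several genes of granule-bearing blood cells were detected mainly in the knockout libraries. In the same order, the mast cell genes Cpa3, Mcpt4 and Cma1 had 11, 114, 0 and 252 reads, 0, 21, 0 and 15 reads, and 0, 35, 0 and 7 reads. The neutrophil genes Ngp, S100a8 and S100a9 had 1, 83, 53 and 284 reads, 0, 7, 16 and 113 reads, and 3, 7, 22 and 103 reads. The megakaryocyte gene Itga2b had 343, 307, 155 and 195 reads and Mpo, of neutrophil precursors, 8, 34, 15 and 0. Kit, expressed by mast cells among others, had 2003, 2212, 2534 and 2492 reads.

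Plvap, a protein of fenestrated endothelium, was lower in the knockout library at E15 (2829 and 1714 reads, log2 -0.78) and higher at E18 (191 and 814 reads, log2 1.79), and between stages in the wild type it had a log2 ratio of -3.94. Gclm had log2 ratios of 2.28 at E15 and 0.71 at E18, whereas the whole antioxidant list had medians of -0.01 and 0.12, inside the central 95% at both stages. The differences between stages were not tested.

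The knockout library at E18 had more genes at 0 reads (1606) than the wild-type library (665), although it was the deepest of the 4. Of 1480 genes with 50 to 99 reads in the wild-type library at E15, 88 (5.95%, exact 95% interval 4.8 to 7.27) had 0 reads in the knockout library at E18, and 15 (1.01%) in the wild-type library at E18. Genes called lower at E18 had a median GC content of 48.0% (percentile 0.0 among random sets of genes), against 49.4% for genes that were not called. At E15 the medians were 50.1% for genes called higher (percentile 92.7, inside the central 95%) and 49.3% for those not called. Genes called lower at E15 also stood at 49.3% (percentile 27.8). Between stages in the knockout they were 51.0% for genes called higher and 48.5% for genes called lower.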
